A study of Drosophila melanogaster with 6 samples.

How the data were processed

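Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Drosophila melanogaster embryos with an antibody against Suppressor of Hairless, Su(H). Per the labels, 3 ChIP libraries and 3 input DNA libraries were made from a y; cn bw sp strain at the stage named embryo 0-8. The antibody was a rabbit polyclonal raised against an epitope within amino acids 259 to 594. The embryos were cross-linked in 1.8% formaldehyde for 15 min, per the labels' protocols. The stage label and the protocol text differ: the protocol speaks of an egg laying of 8-16 hours and of flies laying for 8 hours. The label was followed here, and the sex of the embryos is given as unknown.

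The values used here came from 1 peak list for the whole series. Per the file headers, its coordinates are on FlyBase release 5, and its source column names MACS. The submitters' processing notes name CASAVA versions 1.7.0.2 and 1.7.0.3, BWA, MACS2 and the build BDGP5, without saying which step each served. The authors deposited 1 score per peak, called the MACS score below after the source column. Neither the file nor the labels say whether this score is an enrichment or a transformed p-value, so it was used to describe, rank and filter peaks within the list. Other uses rest on its scale: sums of scores rank runs of peaks, and the closing section multiplies scores by a factor in 1 calculation. The threshold at which peaks were called, and whether and how the 3 ChIP and 3 input libraries were combined, are not given in the sources used here. The list names no library. It therefore holds no value per replicate, no standard deviation between libraries could be formed, and the depth of each library is unknown. Binomial intervals and the interval of the heterochromatin density ratio cover counting error only and treat peaks as independent, and the bootstrap intervals cover the spread between 1 Mb bins.

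The list was read as deposited, with positions counted from 1. Sequences were divided into the 6 chromosome arms (2L, 2R, 3L, 3R, 4 and X), the placed heterochromatin scaffolds of release 5 (names ending in Het), the unplaced scaffold collections U and Uextra, and the mitochondrial genome. No sequence of release 5 was used here, so lengths were replaced by the span from the first to the last peak of each sequence, and densities are peaks per Mb of that span. The gene table at hand is on Release 6, and coordinates of the 2 releases were not mixed. For this reason peaks are named by position alone. The planned comparisons with gene annotation, with the Su(H) binding motif, with tRNA genes and with 15 gene lists were not run. The planned exact binomial test of peaks per arm also needs arm lengths and was replaced by a permutation of 1 Mb bins.

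Peaks with a neighbour within 5 kb (edge to edge) were counted on the 6 arms. They were compared with 1000 random placements of the same peaks within the span of each arm, keeping peak widths and the smallest observed gap. Two-sided permutation p-values cannot fall below 0.002 in this test. In a test on simulated data with 1000 placements, 0 of 40 sets of randomly placed peaks and 20 of 20 sets with 10% planted neighbours passed the 0.05 threshold. A first simulation, with peaks starting on a 2 kb grid, had passed it in 25 of 40 sets, and was replaced by continuous positions that keep the smallest gap, as the random placements do. As the simulated and the random placements follow nearly the same rule, few passes were to be foreseen for sets without planted neighbours. Uneven density along the arms was not simulated. Peaks chained by gaps of up to 5 kb are called runs and were ranked by their summed score. Peaks per Mb on X and on the autosomes were compared over 1 Mb bins counted from the first peak of each arm, leaving out the small arm 4. This used a two-sided permutation test with 100000 resamples and a bootstrap interval of 10000 draws over bins. Scores and widths of 2 sets of peaks were compared by permuting ranks 100000 times, and the smallest p these permutations can give is 1e-05. Correlations are Spearman coefficients across peaks, which are not independent replicates. Benjamini-Hochberg adjustment was applied within each family of tests.

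Named items followed a rule fixed before the data were examined: the 20 peaks with the highest score and the 5 windows of 50 kb, moved by 10 kb, with the most peaks, ties going to the higher summed score. Both were taken from the 6 arms, a restriction that the rule itself did not state. Alternatives were the 50% and the 20% of the peaks with the highest score, all sequences instead of the 6 arms, merging of overlapping peaks, and neighbour distances of 2 and 20 kb. The runs, the bin permutation, the score and width comparisons, the correlations, the joining of peaks across gaps of up to 1 kb and the ranking by width were added after the data were seen, as was the ranking of runs by their highest single score. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and matplotlib 3.10.9 for the figures.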

Results

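Su(H) is the DNA-binding transcription factor of the Notch signalling pathway in flies. It acts with the Notch intracellular domain at activated target genes and with co-repressors in its absence. The series asked where this protein is bound along the genome of the early embryo, with 3 Su(H) ChIP libraries and 3 input DNA libraries. The data analysed here were 1 list of 4403 peaks for the whole series, which does not say which libraries entered the peak calling. Peak widths ranged from 201 to 13028 bp with a median of 355 bp, and no peaks overlapped. The MACS score, whose scale is not stated, had a median of 16.18 and an interquartile range of 12.0 to 23.87. The lowest score was 6.42 and the highest 828.88. The read depth behind the individual peaks is unknown.

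The first question was on which sequences the peaks lay. The 6 chromosome arms held 2074 peaks, which is 47.1% of the list (exact 95% binomial interval 45.6 to 48.6%). Uextra, a collection of scaffolds that release 5 could not place on a chromosome, held 2082 peaks or 47.3% (45.8 to 48.8%). The unplaced collection U held 134 peaks, the placed heterochromatin scaffolds 104 and the mitochondrial genome 9. Per Mb of span, Uextra carried 72.01 peaks, against 17.71 on the arms and 13.53 on U. The placed scaffold 3LHet carried 16.04 peaks per Mb, 3RHet 13.94 and 2RHet 11.15.

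**Figure D1:**
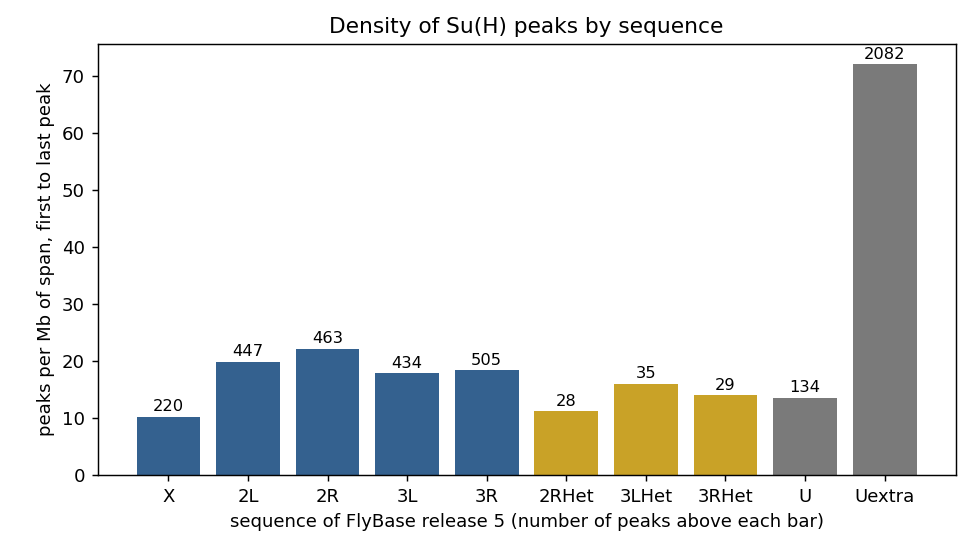
Peaks per Mb of span (first to last peak) for each sequence of FlyBase release 5, with the number of peaks above each bar; blue bars are chromosome arms, yellow bars placed heterochromatin and grey bars unplaced scaffolds. Uextra reached 72.01 peaks per Mb, and X with 10.24 lay below the 4 large autosomal arms. Arm 4 and sequences with spans under 1 Mb are left out.

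Peaks on Uextra had higher scores than those on the arms, with medians of 19.61 and 13.47 (two-sided permutation test of ranks, p = 1e-05, the smallest it can give, and 6e-05 after adjustment over 6 comparisons). In 70.9% of pairs the Uextra peak had the higher score. Of the 889 peaks in the top 20% of all scores, 607 lay on Uextra (68.3%) and 223 on the arms (25.1%). The very highest scores were on the arms, where the maximum was 828.88, against 181.66 on Uextra. Widths differed little, with medians of 354 bp on Uextra and 351 bp on the arms. The test of ranks went the other way from the medians, as the Uextra peak was the wider in 47.5% of pairs (permutation p = 0.0055, adjusted 0.011). In the top 20% of scores of each set the medians were 484 bp on Uextra and 610 bp on the arms. Placed heterochromatin peaks were wider than arm peaks, with a median of 428.5 bp (permutation p = 0.00014, adjusted 0.00042), while their median score of 14.22 was not distinguishable from that of the arms after adjustment (permutation p = 0.043, adjusted 0.065).

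Among the arms, 3R held 505 peaks, 2R 463, 2L 447, 3L 434, X 220 and the small arm 4 only 5. X was sparser than the autosomes: a 1 Mb bin of X held 10.1 ± 8.1 peaks (SD, n = 21 bins) and a 1 Mb bin of 2L, 2R, 3L and 3R together 19.18 ± 9.45 (SD, n = 93 bins). The ratio of X to autosomes was 0.53 (95% bootstrap interval 0.37 to 0.74), and so large a difference in means was rare when bins were reassigned at random (two-sided permutation test, p = 0.0001). The test treats bins as independent and does not measure the spread between whole arms, of which X is a single one. The difference, X minus autosomes, of -9.09 peaks per bin was close in size to the SD between bins, and the bins of X and of the autosomes overlapped. The bin means of the single autosomal arms lay between 17.71 for 3L and 21.3 for 2R. One bin, X 19323898 to 20323897, held 40 of the 220 X peaks, whereas the next fullest bin of X held 18. Without that bin the ratio was 0.45. The fullest bins of the other arms were 2L 6087449 to 7087448 with 47 peaks, 3R 2001165 to 3001164 with 43 and 2R 2139037 to 3139036 with 38. On 3L the bin 5131568 to 6131567 held 39 peaks and tied with another. The peaks that X did carry had scores not distinguishable from those of the autosomal arms, with medians of 13.91 and 13.47 (permutation test, p = 0.62, adjusted 0.62). The X peak ranked higher in 51.0% of pairs.

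**Figure D2:**
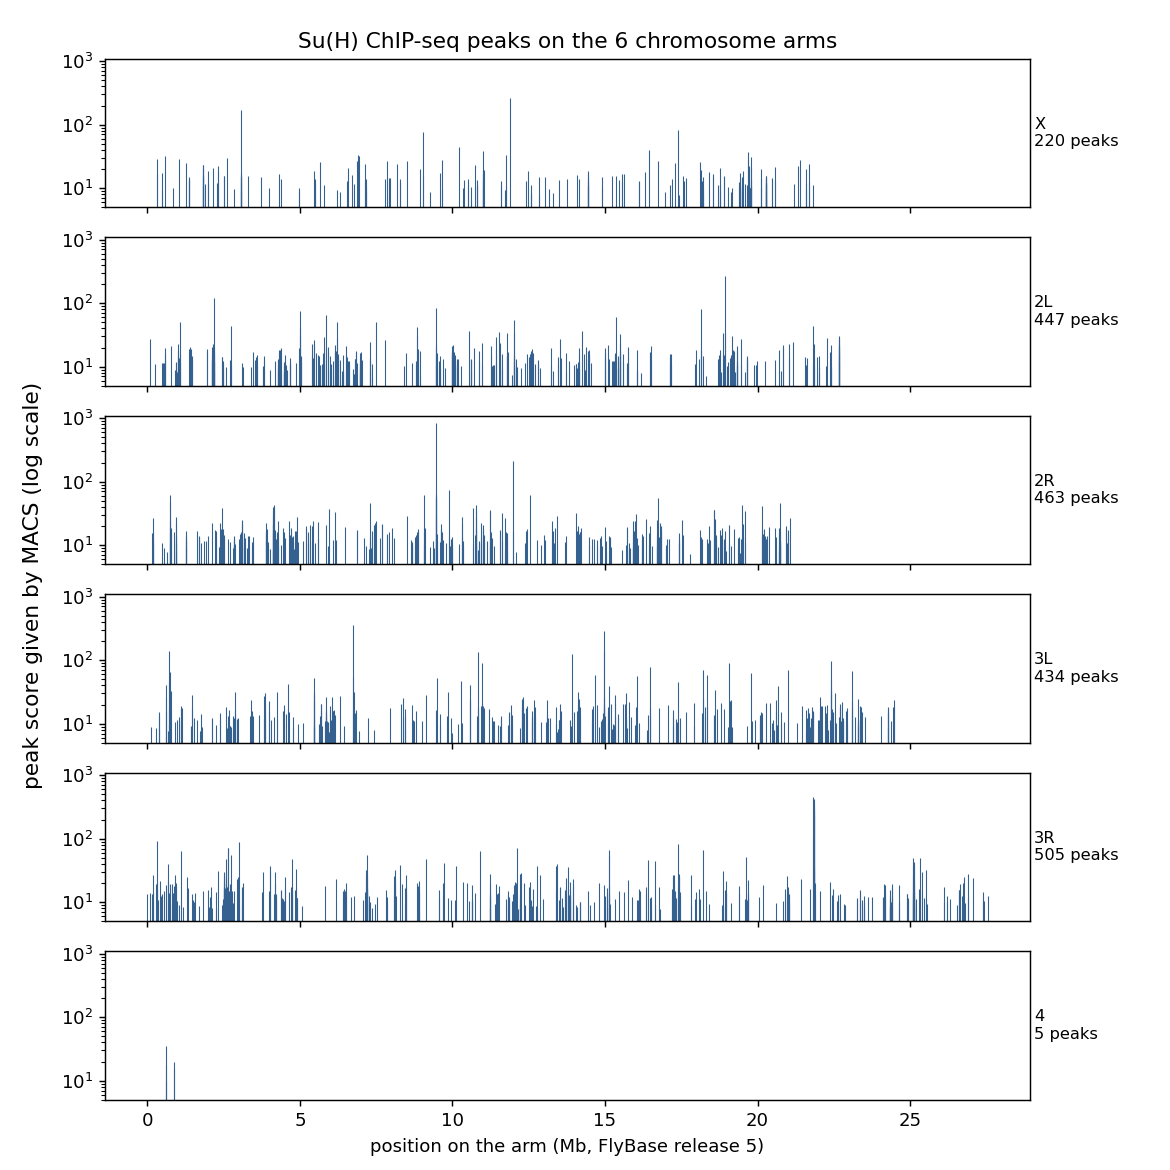
Every peak on the 6 chromosome arms, drawn at its midpoint (Mb, FlyBase release 5) with a line up to its MACS score on a log axis. The interquartile range of these scores is 10.79 to 18.1, and the tallest lines on 2R and on 3R, up to 828.88 and 445.63, belong to the 2 runs with the highest summed score.

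The second question was whether peaks lay singly or in groups. On the arms 1057 of the 2074 peaks (51.0%) had another peak within 5 kb. Random placement gave 347.3 such peaks on average and 426 at most in 1000 placements, so that the observed number was 3.04 times the random mean (two-sided permutation p = 0.002, the smallest it can give). These placements spread peaks evenly along each arm, whereas single 1 Mb bins held from 2 (on 3R) to 47 peaks (on 2L). The excess may therefore include uneven density along the arms, and grouping particular to Su(H) was not tested. Over all sequences the ratio was 1.66, with 2452 of 4403 peaks (permutation p = 0.002). That count includes U and Uextra, where neighbours may lie on separate scaffolds, so it need not reflect distances in the genome. After joining gaps of up to 1 kb on the arms, 511 of 1688 peaks (30.3%) had a neighbour, 2.64 times the random mean (permutation p = 0.002). For the peaks as deposited, each of the 5 large arms exceeded random placement, with ratios of 3.16 for 2L, 2.64 for 2R, 2.67 for 3L, 3.11 for 3R and 5.25 for X (permutation p = 0.002 and adjusted p = 0.002 for each). As a share of peaks with a neighbour, X with 50.5% lay between 3L with 43.1% and 2L with 56.2%. Its higher ratio goes with its sparse peaks, since random placement of its 220 peaks gave only 21.2 with a neighbour on average. Neighbouring peaks formed 377 runs of 2 or more, of which 38 had at least 5 peaks and 13 had at least 7. The remaining 1017 peaks stood alone.

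The most extensive run lay on 3R from 21821675 to 21867764. Its 13 peaks covered 39.9 kb of 46.1 kb, and the next most populous run on any arm had 9 peaks. It had the highest summed score on the arms, 2274.88. Once gaps of up to 1 kb were joined, or when runs were ranked by their highest single peak, it came second to the run on 2R. Of its peaks, 6 scored above 200. These were 21824615 to 21833378 (score 445.63), 21849619 to 21854029 (423.21), 21833560 to 21837513 (364.86), 21842250 to 21848449 (305.32), 21854718 to 21863528 (283.69) and 21864535 to 21866619 (224.94). A further 6 of the 13 peaks scored below 40, and 4 of these lay side by side between 21837826 and 21842198.

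The run with the second highest summed score lay on 2R from 9447397 to 9472450 and held 7 peaks. Its first peak, 9447397 to 9460424, was both the widest (13028 bp) and the highest scoring (828.88) of the whole list. The other 6 peaks of that run scored between 12.62 and 62.8. The third run, on 3L from 14960789 to 14972917, held 5 peaks, and its strongest were 14967465 to 14969078 (score 289.92) and 14970477 to 14972917 (138.38).

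**Figure D3:**
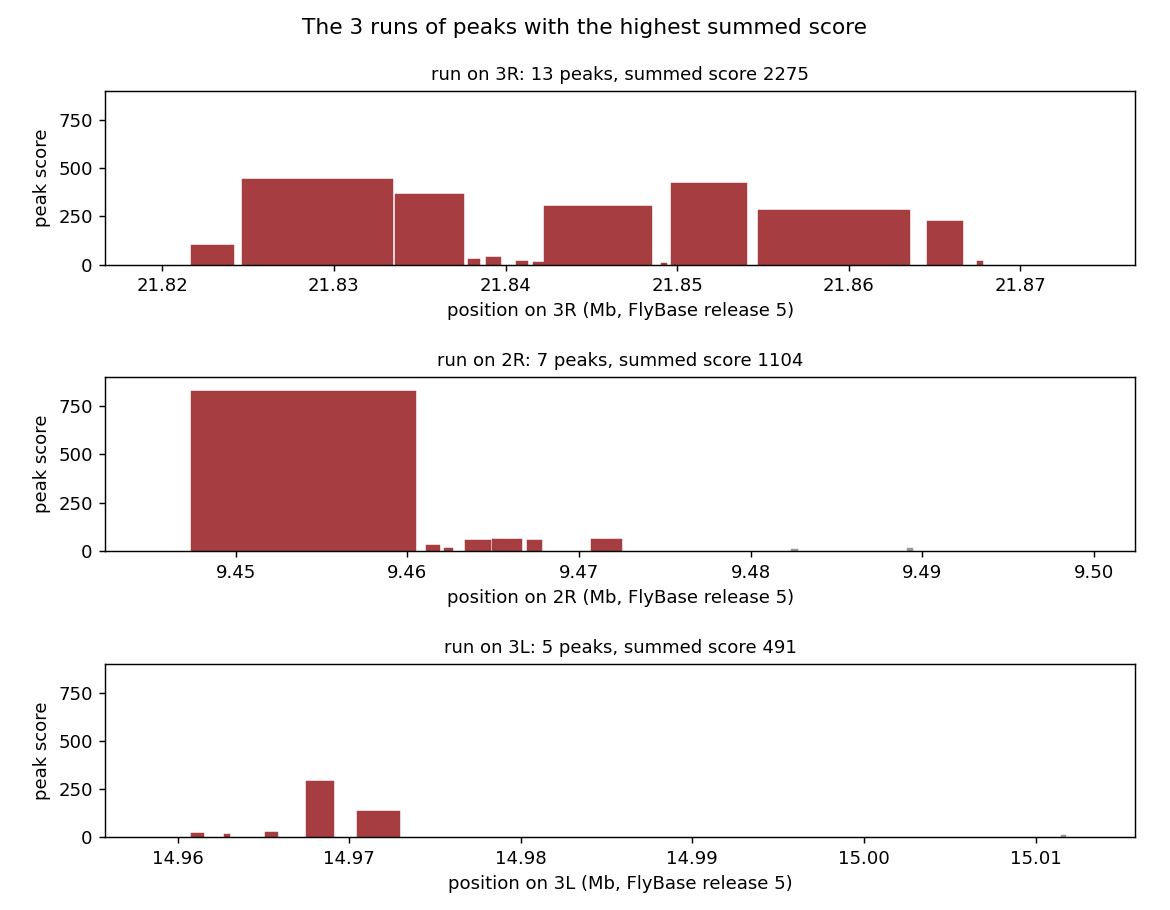
Peaks of the 3 runs with the highest summed score, with panels of equal length (FlyBase release 5); each rectangle spans 1 peak, its height is the MACS score, and grey marks peaks outside the run. The 3R run fills 39.9 kb with 13 peaks, whereas the 2R run consists mainly of 1 peak with a score of 828.88.

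The 20 highest-scoring arm peaks were spread over 5 arms, with 7 each on 3L and 3R and 2 each on 2L, 2R and X. The 3R run accounted for 7 of them, the 3L run for 2 and the 2R run for 1. Another 5 stood alone, without a neighbour within 5 kb. These single peaks were 3L 6736704 to 6737365 (score 355.71, width 662 bp), X 11901181 to 11903793 (265.26), X 3056091 to 3057171 (168.82), 3L 699036 to 699857 (140.04) and 3L 13912913 to 13913798 (122.93). Strong peaks with weaker neighbours were found at 2L 18945810 to 18948074 (score 269.76), 2R 11996878 to 11998725 (213.88), 3L 10849216 to 10850385 (134.06), 2L 2181338 to 2182363 (120.39) and 3L 22401043 to 22401520 (97.35).

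Counted by number of peaks alone, the fullest 50 kb regions were 3R 21820001 to 21870000 and 3R 25080001 to 25130000 with 13 peaks each. The next were 3R 20970001 to 21020000 with 12, and 2R 4090001 to 4140000 and 2R 15910001 to 15960000 with 11 each. The first of these, which contains the 3R run, differed from the others in score. Its highest peak scored 445.63, whereas no peak of the other 4 regions exceeded 49.71. When peaks separated by gaps of up to 1 kb were joined, the first region kept 2 peaks and the second 8, the third 8, the fourth 6 and the last 9. The fullest regions were then 2R 20700001 to 20750000 and 2R 15910001 to 15960000 with 9 joined peaks each, and 3 of the 5 regions were others than before.

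Higher-scoring peaks were wider. Across the 2074 arm peaks the Spearman correlation of score and width was 0.61, and across the 2082 Uextra peaks it was 0.59 (permutation p = 1e-05 for both, the smallest it can give, adjusted 3e-05 over 6 relations). On the arms 17 peaks were wider than 2 kb. Adjacent arm peaks within 5 kb had weakly related scores (Spearman 0.12 over 680 pairs, permutation p = 0.0017, adjusted 0.0034). Once gaps of up to 1 kb were joined, 294 pairs were left and the correlation was no longer past the threshold (Spearman 0.07, permutation p = 0.25, adjusted 0.29). For adjacent peaks farther apart the correlation was 0.03 over 1388 pairs (permutation p = 0.29, adjusted 0.29).

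**Figure D4:**
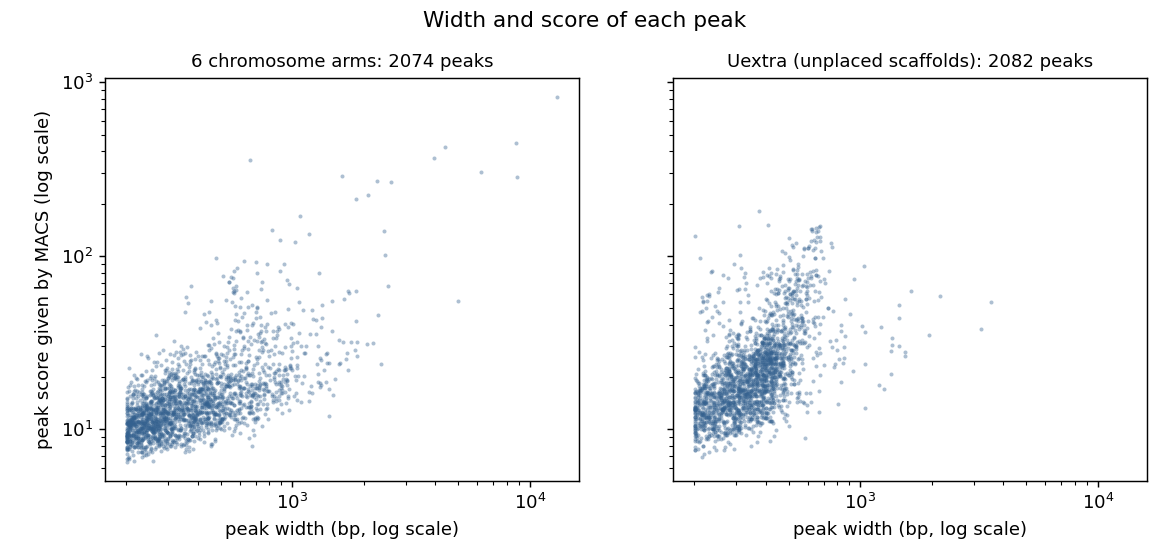
Width (bp) and MACS score of each peak on log axes, 1 point per peak, for the 2074 peaks of the chromosome arms and the 2082 peaks of Uextra. Only the arms have points above a score of 200, and the higher-scoring Uextra peaks form a narrow band of widths.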

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

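The tests in this part were chosen after the peak list had been seen. The peaks outside the chromosome arms were singled out because the main comparisons of positions used the arms alone. They comprised 2082 peaks on Uextra, 134 on U, 104 on placed heterochromatin scaffolds and 9 on the mitochondrial genome. On the placed heterochromatin scaffold XHet, all 8 peaks lay between 190413 and 203916. Its strongest peak, 196013 to 197596, scored 123.98, while the highest score on 3LHet was 126.08. The 9 mitochondrial peaks had a median score of 39.26 and lay between 1423 and 19116.

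The share of peaks on Uextra was the most conspicuous pattern. General enrichment of Su(H) ChIP DNA over heterochromatin would give placed heterochromatin a similar density, if peaks can be called equally well on both. The placed scaffolds (103 peaks without YHet, which had 1) carried 14.67 peaks per Mb of span, 0.2 of the Uextra value (exact 95% interval 0.17 to 0.25). Under that condition, which was not tested, this argues against an enrichment that the placed scaffolds share. An enrichment limited to unplaced heterochromatin was not tested. Sequences present in many unplaced copies are a candidate explanation: in the top 20% of scores of each set, 44.7% of Uextra peaks had widths of 397 to 546 bp, while the fullest 150 bp width class on the arms held 22.9%, a ratio of 1.95 (permutation p = 1e-05, the smallest it can give). Short scaffolds could also narrow the widths, and neither sequence nor read depth was available to decide between these. No other biological explanation was tested for this pattern.

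The lower density on X was the next pattern. Male embryos carry a single X, so in a mixed collection X would be sequenced at lower depth, which may leave fewer peaks above the calling threshold. If autosomal scores are multiplied by 0.75, as for equal numbers of both sexes, the predicted X to autosome ratio is 0.51 above the median score, where 0.59 was observed (95% bootstrap interval 0.43 to 0.79). Over all scores down to the lowest autosomal one the prediction is 0.92, above the observed 0.53 (0.37 to 0.74), and the called X peaks would have a median score of 10.51, where 13.91 was observed. The latter values take the lowest autosomal score, 6.57, as the calling threshold, while the lower quartile of autosomal scores was 10.79. The prediction thus depends on the score chosen as the threshold. The calculation also assumes that scores scale with depth and that peaks were called down to 1 score. The file states neither, so the calculation cannot decide. Lower depth, as the whole or a part of the cause, and a true difference between the arms stay open.

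The third pattern was the run of 13 peaks on 3R. A single broad enriched region split by the peak caller may account for the number of peaks, and joining gaps of up to 1 kb left 2 peaks there. As the peaks already covered 39.9 kb of 46.1 kb, joining would leave few peaks whether or not the region is single. The joining therefore cannot decide. Counting the peaks separately raises the summed score. With joined peaks carrying their highest score, the sum was 670.57 over 45.1 kb covered, second to 889.81 for the run on 2R. Whether the copy number of this region was unusual could not be examined without values for the input libraries.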

How the results depend on the processing

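The clustering of arm peaks kept its direction and stayed past the threshold at neighbour distances of 2 and 20 kb. It also did so in the 50% and in the 20% of the peaks with the highest score. Ratios to random placement ran from 1.41 (neighbours within 20 kb) to 7.19 (the 20% of the peaks with the highest score). In that 20%, the share with a neighbour was 24.8%, below the 51.0% of all arm peaks, and the random share was 3.5%. Keeping fewer peaks lowers both shares by itself. Neither the shares nor the higher ratio can therefore show whether high-scoring peaks group more closely. Merging overlapping peaks changed no peak, and over all sequences the ratio was 1.66. It was 2.64 on the arms after joining gaps of up to 1 kb, an alternative chosen after the data were seen. The X to autosome ratio stayed between 0.51 and 0.59 in its 3 alternatives, and was 0.45 without the fullest X bin. The Uextra share of 47.3% rose to 62.3% in the 50% and to 68.3% in the 20% of the peaks with the highest score. Merging overlapping peaks left 4403 peaks, joining gaps of up to 1 kb left 3781, and restriction to the 6 arms left 2074. With all sequences included, the fullest 50 kb region held 25 peaks and lay on Uextra, against 13 on the arms and 9 on the arms after joining gaps of up to 1 kb. As U and Uextra are collections of scaffolds, windows, neighbours and joined peaks there may span separate scaffolds. Their counts, and the ratio of 1.66, need not reflect distances in the genome. Of the 20 top arm peaks, 13 remained among the 20 highest of all sequences and 11 among the 20 widest of the arms. The median width of arm peaks rose from 351 to 610 bp and that of Uextra peaks from 354 to 484 bp in the 20% of peaks with the highest score. The correlation of adjacent scores fell to 0.07 (permutation p = 0.25) after joining, where 294 pairs were left. The alternatives planned for the annotation, motif, gene list and tRNA comparisons were not run. No library could be left out in turn, because the list holds no values per library. No paired analysis was possible because the list does not separate the replicates. The unknown depth limits what the absence of a peak can show.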

Other observations

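Both tests in this part bear on hypotheses. The test of adjacent scores was set before its result was known, and the test of gene complexes afterwards. The highest-ranking runs are candidates for known Notch target clusters. The Enhancer of split complex, a cluster mainly of bHLH repressor and Bearded family genes activated by Notch, lies on 3R. All 12 of its genes in a list fixed beforehand were found on that arm in the Release 6 gene table. Of the 6 listed genes of the Bearded complex, 4 were found, all on 3L. The hypothesis is that the runs hold the E(spl) and Bearded gene complexes. The run of highest summed score, as deposited, lay on 3R and the 5-peak run on 3L, so that 2 of 2 complexes were on the arm of their run. The runs were paired with the complexes after the peak list had been seen, passing over the second-ranked run on 2R. The match of arms was settled by this pairing and is no evidence for the hypothesis. Each arm also holds a large part of the genome, and with no gene positions on release 5 the identity of the runs stays open. The other of the 3 leading runs, 2R 9447397 to 9472450, has no candidate here.

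A second hypothesis was that a few large runs carry the weak correlation between the scores of adjacent peaks. Without the 2 runs of highest summed score the Spearman correlation was 0.09 over 662 pairs (permutation p = 0.018, adjusted 0.027), against 0.12 with them. This met the bound of 0.1 set beforehand, but only narrowly. The 662 pairs are part of the 680 used before, and no error was computed for either correlation or for the change. The test therefore could not decide.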
